A study of Homo sapiens with 9 samples.

How the data were processed

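RNA from MCF-7 breast cancer cells was profiled on 9 Affymetrix Human Exon 1.0 ST arrays, which carry probes for the exons of known genes. Per the labels, cells were kept in medium with 5% serum, then for 3 days without phenol red in serum stripped of steroids with charcoal, before transfection of 5 nM miRNA and exposure to 10 nM estradiol, and RNA was taken 48 h later. Groups and replicate numbers were taken from the sample titles, which name biological replicates. The protocol text repeats the estradiol step for every sample, whereas the titles name vehicle for 3 of them, and the titles were followed. The titles, not the protocol text, are thus the basis of the estradiol comparison.

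The authors deposited 1 log2 value per transcript cluster and array, 22011 clusters on 9 arrays. Per the labels, probes were grouped by the exon array's library file and its core gene-level list on human build hg18. The summarisation and normalization methods are not given in the sources used here. That the values are log2 was read from the values themselves, which lay between 1.97 and 14.4. The arrays' distributions were similar but not identical, so no quantile step had been applied after summarisation. Per the series design, the authors made both pairwise comparisons with EASANA (GenoSplice) and kept folds of at least 1.5, and no test is stated. Array data give no read depth, and the number of arrays limits the precision.

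Gene names came from the platform annotation and were updated through a table of human genes (assembly GRCh38.p14), and no coordinates from that table are given because the builds differ. Of the clusters, 14432 had 1 gene symbol, 2408 had several and 5171 had none, and only those with 1 symbol were named. For 28 gene identifiers the table had no match, and the annotation's symbol was kept. The named clusters stood for 14232 genes, and for the 200 further clusters of a gene already named the cluster with the highest mean over all arrays was used. CTDSP1, CTDSP2, CTDSPL and STAT1 lay on clusters with several genes or none and were not analysed here. Exon arrays can cross-hybridise between near-identical paralogs, which affects ribosomal protein genes, of which 9 of the listed ones had a cluster of their own.

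The values were used as deposited, without further normalization. Differences were tested with limma (version 3.58.1, R 4.3.3) by lmFit and eBayes with a two-sided moderated test and Benjamini-Hochberg adjustment over all 22011 clusters in each comparison. All 3 groups were fitted together with group as the only term, so that they shared 1 estimate of the spread with 6 residual degrees of freedom. The threshold was an adjusted p of 0.05, alone or with a fold of at least 1.5. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the 20 lists of a comparison; the same test with an estimated correlation stands beside it. List counts are given over all genes and adjusted over the list alone. Overlap between the comparisons was set beside 100 simulations of unchanged groups that share the control arrays.

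The comparisons, tests, 20 gene lists, naming rule and most alternatives were fixed before the data were examined. The lists cover estrogen-induced and estrogen-repressed genes, G1/S and DNA replication, G2/M and mitosis, literature miR-26a targets, interferon and double-stranded RNA response, the miRNA pathway, p53 targets, estrogen receptor and cofactors, cholesterol synthesis, ER stress and ATF4 targets, polycomb, luminal epithelial, basal and mesenchymal, markers of other cell types, hypoxia, ribosomal proteins, ribosome biogenesis, lysosome and autophagy, and RNA processing. They were written from general knowledge of the field. Lists of leukocyte transcripts and antigen presentation genes were added after the data were seen. The named genes were, per comparison, the 10 largest rises and 10 largest falls among clusters past the threshold with 1 gene symbol and no overlap between groups, up to 4 members of smallest p from each list, and a fixed set (ESR1, PGR, GREB1, TFF1, MYC, CCND1, EZH2, CCNE1, CCNE2, CDK6, CDKN1A and the CTDSP family). Genes outside that rule are marked as named after their values were seen.

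The alternatives were the replicate number as a block, quantile normalization, arrays centred on their medians, a milder and a stricter filter on dim clusters, a trended and robust variance prior, only the 6 arrays compared, array weights, each array left out in turn, other fold thresholds, an estimated correlation, and the mean of all clusters of a gene. A covariate for array spread and a fit without 2 arrays of the control miRNA with estradiol were added after the data were seen. The steps were tested on simulated data with 200 changed clusters per comparison among 22011. In the miR-26a comparison 42 of 100 clusters changed 1.5-fold and 85 of 100 changed 2-fold were recovered with 6 false calls, and in the estradiol comparison 47 of 100 and 75 of 100 with 4 false calls. Every simulated group had the same spread per cluster. In the data the median SD was 0.193 in the control miRNA group with estradiol, 0.094 with miR-26a and 0.08 with vehicle. False calls may thus be understated. In each comparison 1 raised list was recovered among 14232 genes and 0 lists sharing none of its genes were called. Genes were simulated independently, whereas the estimated correlation within the real lists reached 0.818. The list result therefore does not show how often camera at the preset correlation calls real lists falsely.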

Results

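Gene expression was measured in MCF-7 cells, an established line of estrogen receptor-positive breast cancer, after transfection of miR-26a or a control miRNA. MicroRNAs are short RNAs that lower the level or translation of transcripts they pair with. The 9 arrays fell into 3 groups of 3 biological replicates: miR-26a with estradiol, control miRNA with estradiol, and control miRNA with vehicle. The series design sets the miR-26a group against the control miRNA under estradiol, and estradiol against vehicle with the control miRNA. The first asks what miR-26a changes in estradiol-treated cells, and the second what estradiol changes without miR-26a. Each array gave 22011 log2 values, one per transcript cluster, which is the array's unit for a gene, and the number of arrays limits the precision. Median values lay between 7.34 and 7.55. The 3 control miRNA arrays with estradiol stood apart from one another, with interquartile ranges of 2.59, 2.44 and 2.83 in replicates 1, 2 and 3 against 2.62 to 2.77 on the other 6 arrays. Their correlations across transcript clusters, which are not independent replicates, were 0.963 to 0.989. Replicate 3 correlated at 0.9877 to 0.9905 with the vehicle arrays, above its 0.9816 and 0.9633 with replicates 1 and 2 of its own group. The median SD per cluster was 0.193 in the control miRNA group with estradiol, against 0.094 in the miR-26a group and 0.08 with vehicle. The control miRNA group with estradiol enters both comparisons, and the spread pooled over the 3 groups is lower than its own.

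Transfection of miR-26a under estradiol was accompanied by a strong rise of interferon-response genes. IFIT2, an antiviral protein that binds viral RNA (transcript cluster 3257192), rose at least 92.7-fold, from 5.70 ± 0.40 to 12.23 ± 0.14 (log2, mean ± SD, n = 3 per group; log2 difference 6.54, SE 0.199, limma adjusted p = 1.53e-06). Its neighbour in function IFIT3 rose 67.5-fold, and CXCL10, a chemokine that attracts T cells, rose at least 49.1-fold from 4.11 ± 0.27 to 9.72 ± 0.25. The mean control levels of IFIT2, CXCL10, RSAD2, IFI44L, IFI44, TRIM22, TNFSF10 and TLR3 lay under the 25th percentiles of the arrays (6 to 6.06), although IFIT2 reached 6.11 on replicate 3. Expression there was not separated from background, so their folds are minimum values. All 27 measured members of the interferon and double-stranded RNA list rose over all genes tested and adjusted over the list alone, with a median log2 difference of 3.98, and 26 of them passed after either scaling of the arrays. RSAD2, which inhibits virus assembly, rose 19.9-fold (adjusted p = 4.37e-07), and the RNA sensors RIGI, IFIH1 and TLR3, named after their values were seen, rose by log2 differences of 3.98, 3.65 and 2.25. Of the other genes among the 10 largest rises, IFIT1, IFI44L, OAS2, IFI44, TRIM22 and IFI27 are interferon-induced, and TNFSF10, the death ligand TRAIL, rose 21.1-fold. Per-array means of the list were 10.56 ± 0.12 with miR-26a and 6.89 ± 0.20 with the control miRNA, without overlap. The exact permutation p was 0.1, the smallest that 3 arrays against 3 allow. The list was higher by limma's camera test, a competitive test of a gene list against all other genes (adjusted p = 2.83e-59), and it was the 1 list of 20 in this comparison whose call held with an estimated correlation between genes (adjusted p = 0.00735).

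DNA replication genes were lower with miR-26a. Of 39 measured members of the G1/S and DNA replication list, 12 fell over all genes and 28 adjusted over the list alone, none rose, and the median log2 difference was -0.46 (camera adjusted p = 2.66e-21; adjusted p = 0.331 with an estimated correlation). Without replicate 2 of the control miRNA with estradiol the median was -0.73. MCM2, a subunit of the replicative helicase, fell from 10.20 ± 0.14 to 9.46 ± 0.03 (log2 difference -0.74, SE 0.082, adjusted p = 0.0016, n = 3 per group), and MCM5 of the same complex differed by -0.73. The thymidylate synthase gene TYMS fell by 0.89 on the log2 scale, UHRF1, which helps copy DNA methylation, by 0.90, and CDC45, a partner of that helicase, by 0.93 (adjusted p = 0.00591). DTL, a substrate receptor of a ubiquitin ligase active in S phase, fell by 1.21 (adjusted p = 0.0129), but its call was lost without miR-26a replicate 3 (0.0597) or replicate 1 of the control miRNA with estradiol (0.0527). Of 35 G2/M and mitosis genes, 4 fell and 8 did so adjusted over the list alone, with a median of -0.35 (camera adjusted p = 2.15e-11; adjusted p = 0.467 with an estimated correlation). The median was -0.54 and -0.14 without replicates 2 and 3 of the control miRNA with estradiol. Against vehicle it was -0.30 with 0 of 35 genes called. That comparison was added after the data were seen, and in it estradiol differs as well as the miRNA. The mitotic kinase gene AURKB fell by 0.42, the survivin gene BIRC5 by 0.50, the securin gene PTTG1 by 0.37 and the mitotic transcription factor gene FOXM1 by 0.67. The calls of BIRC5, PTTG1 and FOXM1 were lost without any 1 of the 3 miR-26a arrays or without replicate 1 of the control miRNA with estradiol. That of BIRC5 was also lost without vehicle replicate 2, that of PTTG1 without vehicle replicate 3 and that of FOXM1 without any vehicle array (adjusted p up to 0.0959, 0.11 and 0.134). Per-array means of the mitosis list overlapped between the groups, at 8.83 ± 0.11 and 9.19 ± 0.39 (exact permutation p = 0.3).

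Stress and cell death genes rose in part. Of 19 p53 target genes, 5 rose and 6 did so adjusted over the list alone, with a median log2 difference of 0.14 (camera adjusted p = 0.000399; adjusted p = 0.514 with an estimated correlation). The median was 0.04 and 0.26 without replicates 2 and 3 of the control miRNA with estradiol, and 0.07 after either scaling or with the arrays' interquartile range as a covariate. Against vehicle the p53 list did not pass, with a median of -0.04, a mean of 0.107 and an upward camera direction (adjusted p = 0.471). PMAIP1, which encodes the pro-apoptotic protein NOXA, rose 4-fold (adjusted p = 0.000938), the death receptor gene TNFRSF10B 2.16-fold, the growth arrest gene GADD45A 2.13-fold and CDKN1A, an inhibitor of cyclin-dependent kinases, 1.82-fold (adjusted p = 0.00438). The fifth was the death receptor gene FAS (log2 difference 0.89), which was named after its value was seen. FAS, BTG2 and TP53INP1 are also on the estrogen-repressed list. Of 23 ER stress and ATF4 target genes, 4 rose and 11 did so adjusted over the list alone, with a median of 0.29 (camera adjusted p = 3.03e-07; adjusted p = 0.418 with an estimated correlation). That median was 0.19 after quantile normalization and 0.18 without replicate 2 of the control miRNA with estradiol. PPP1R15A, which directs a phosphatase to eIF2α, rose by 1.31 on the log2 scale, the mTORC1 inhibitor gene DDIT4 by 0.80, SDF2L1 by 0.69 and the chaperone gene HSPA5 by 0.71. The HSPA5 call was lost in 8 of the 9 fits that left out 1 array, all but the one without replicate 3 of the control miRNA with estradiol (adjusted p up to 0.155).

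Estrogen-repressed genes were higher with miR-26a, while estrogen-induced genes went both ways. Of 27 estrogen-repressed genes, 8 rose over all genes; adjusted over the list alone, 13 rose and 1 fell, with a median log2 difference of 0.23 (camera adjusted p = 7.79e-09; adjusted p = 0.244 with an estimated correlation). The median was 0.14 after quantile normalization and 0.36 without replicate 3 of the control miRNA with estradiol. The transcription factor gene KLF4 rose 3.88-fold, the adhesion scaffold gene NEDD9 3.80-fold, the growth factor gene TGFB2 3.09-fold and the transcriptional coregulator gene CITED2 1.94-fold. Of 35 estrogen-induced genes, CA12, a carbonic anhydrase gene, rose by 0.66 and MICB, a ligand of a natural killer cell receptor, by 0.48, and the fatty acid elongase gene ELOVL2 fell by 0.76. Adjusted over the list alone, 5 rose and 5 fell. The list's median was 0.04, its mean -0.004 and the camera direction downward (adjusted p = 0.997), and the median became -0.05 after quantile normalization. The calls of MICB and ELOVL2 were lost without miR-26a replicates 1 or 2, replicate 1 of the control miRNA with estradiol or vehicle replicates 1 or 3. That of MICB was also lost without replicate 2 of the control miRNA with estradiol, and that of ELOVL2 without miR-26a replicate 3 or vehicle replicate 2 (adjusted p up to 0.128 and 0.181). The estrogen receptor gene ESR1 had a log2 difference of -0.14 (adjusted p = 0.51), the progesterone receptor gene PGR -0.54 (0.272; 0.00959 after quantile normalization), TFF1 0.20 (0.238), GREB1 0.06 (0.844; -0.01 with arrays centred on their medians or without replicate 2 of the control miRNA with estradiol), MYC 0.35 (0.0661) and CCND1 0.15 (0.293). PGR also passed without replicate 2 of the control miRNA with estradiol (0.0412). MYC passed after quantile normalization (0.0204), with the stricter filter on dim clusters (0.0481) and without replicate 3 of that group (0.00674) or replicates 2 and 3 (0.0323). Both passed with the arrays' interquartile range as a covariate (0.000562 and 0.00497). With array weights PGR, MYC, ESR1 and TFF1 passed (0.00561, 0.000991, 0.0182 and 0.0352).

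Epithelial and mesenchymal genes changed singly. Of 17 luminal epithelial genes, KRT80, OVOL1, MUC1 and CLDN4 rose by 1.33, 0.85, 0.79 and 1.00 on the log2 scale, and SPDEF and TFF3, named after their values were seen, fell by 0.63 and 0.38. Adjusted over the list alone, 6 rose and 2 fell, and the list did not pass (median 0.11, camera adjusted p = 0.117; 0.049 after quantile normalization). The tight junction gene CLDN4 lost its call without replicate 1 of the control miRNA with estradiol (adjusted p = 0.0505). Of 11 basal and mesenchymal genes, the transcriptional repressor genes SNAI2 and SNAI1 rose by 1.64, from a control level of 5.77 under the arrays' 25th percentile, and by 0.72 and the fibronectin gene FN1 by 1.00, and 4 rose adjusted over the list alone. That list passed with a median of 0.03, which turned to -0.04 when arrays were centred on their medians (camera adjusted p = 0.0253; adjusted p = 0.244 with an estimated correlation), and its call was lost without replicate 3 of the control miRNA with estradiol (0.205). It was also lost without replicates 2 and 3 of that group (0.174), with array weights (0.198) and with the stricter filter on dim clusters (0.748). Its median was 0.09 and 0.02 without miR-26a replicates 2 and 3, 0.04 and 0.05 without replicates 1 and 2 of the control miRNA with estradiol, 0.01 after quantile normalization, 0.06 with the interquartile range covariate and 0.44 with the milder filter on dim clusters. Of 9 ribosomal protein genes RPL4 fell by 0.83, and 3 fell adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.0331; adjusted p = 0.331 with an estimated correlation). This list's call was lost after quantile normalization (0.16), with arrays centred on their medians (0.092), without miR-26a replicate 2 (0.0565) or replicate 3 of the control miRNA with estradiol (0.205). It was also lost without replicates 2 and 3 of that group (0.0953), with array weights (0.0787), with the interquartile range covariate (0.0594) and with the mean of all clusters of a gene (0.0505). The RPL4 call was lost without any array but replicate 3 of the control miRNA with estradiol (up to 0.148).

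The 31 measured genes that the literature names as miR-26a targets did not shift as a group. Over all genes and adjusted over the list alone, 1 of them rose, the collagen cross-linking enzyme gene LOXL2 (log2 difference 0.75, adjusted p = 0.00272), and none fell. The median was 0.03 (camera adjusted p = 0.928), which turned to -0.06 after quantile normalization, with 3 members then called lower. The histone methyltransferase gene EZH2 had a log2 difference of -0.26 (adjusted p = 0.611), and the cell cycle genes CCNE1, CCNE2 and CDK6 had 0.15 (0.66), -0.63 (0.442) and -0.05 (0.8). EZH2 passed after quantile normalization (-0.37, adjusted p = 0.0294) and with the arrays' interquartile range as a covariate (-0.39, 0.000534). CCNE2 passed with that covariate (-0.87, 0.00069) and with array weights (-0.54, 0.0364). Among 15 miRNA pathway genes, 1 rose over all genes and adjusted over the list alone, the interferon-inducible RNA editing enzyme gene ADAR (0.98, adjusted p = 0.00605), and the list median was 0.00 (0.835).

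The remaining lists did not pass in this comparison, but without replicate 3 of the control miRNA with estradiol cholesterol synthesis (0.0213), markers of other cell types (0.0368) and RNA processing (0.0276) did. Cholesterol synthesis had a median of 0.19 over 16 genes (camera adjusted p = 0.117), with STARD4 and HMGCS1 called higher both over all genes and adjusted over the list alone. Hypoxia had 0.17 over 17 genes (0.395), with VEGFA higher and ALDOC lower under both adjustments. The VEGFA call was lost without miR-26a replicates 1 or 2 (adjusted p up to 0.0609), and those of STARD4, HMGCS1 and ALDOC without any miR-26a or vehicle array or replicate 1 of the control miRNA with estradiol, that of HMGCS1 also without replicate 2 of that group (up to 0.129, 0.158 and 0.121). Markers of fibroblasts, endothelium and immune cells had a median of -0.04, a mean of 0.008 and a camera adjusted p of 0.601 over 19 genes, with the macrophage-associated gene CD68 alone higher under both adjustments (0.82). No member passed over all genes or adjusted over the list alone among lysosome and autophagy genes (median 0.14, camera adjusted p = 0.117), RNA processing genes (0.10, 0.429), ribosome biogenesis genes (0.06, 0.928), estrogen receptor and cofactor genes (0.03, 0.997) and polycomb genes (0.04, 0.871), and for the last 2 lists the camera direction was downward against a positive median.

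In total, 893 of 22011 transcript clusters changed with miR-26a at an adjusted p under 0.05, 700 higher and 193 lower (78.4% higher). At a fold of at least 1.5, the size the series design selects, 560 changed, 482 higher and 78 lower. Groups did not overlap in 14.8% of clusters, where chance gives 10% if all arrays vary alike. The unequal spreads of the groups raise that share, so no excess over chance is read from it. The 10 largest falls were led by TMT1A, a thiol methyltransferase gene that fell from 8.86 ± 0.34 to 6.88 ± 0.17 (3.96-fold, SE 0.164 on the log2 scale, adjusted p = 0.000313, n = 3 per group), and ACO1, the cytosolic aconitase and iron regulatory protein gene (2.53-fold, adjusted p = 0.00141). DEPTOR, an mTOR inhibitor gene, fell by 1.08, the mitochondrial carrier gene SFXN2 by 1.03, MLLT11 by 0.95, the calmodulin-binding protein gene PCP4 by 0.94, the exonuclease gene EXO1 by 0.93 and RPL22 by 0.90. After quantile normalization, 1511 clusters were called, 886 higher and 625 lower (58.6% higher), and with arrays centred on their medians 1205, 743 higher and 462 lower (61.7%). At 1.5-fold the shares higher were 86.1%, 71.5% and 74.1%. The count was 558, 544 and 583 without miR-26a replicates 1, 2 and 3, 521 and 3719 without replicates 1 and 3 of the control miRNA with estradiol, and 1363 without replicates 2 and 3 of that group, and at 1.5-fold it was 1641 without replicate 3. With only the 6 arrays compared 437 clusters were called. The arrays' interquartile range as a covariate gave 3182 (54.6% higher), and array weights gave 5817 (65.9% higher) and 1373 at 1.5-fold. Of 60 calls among named genes 45 held whichever array was left out and 15 were lost at least once, among them PCP4 without any miR-26a array (adjusted p up to 0.0754) and EXO1 without these, replicate 1 of the control miRNA with estradiol or any vehicle array (up to 0.119).

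**Figure D1:**
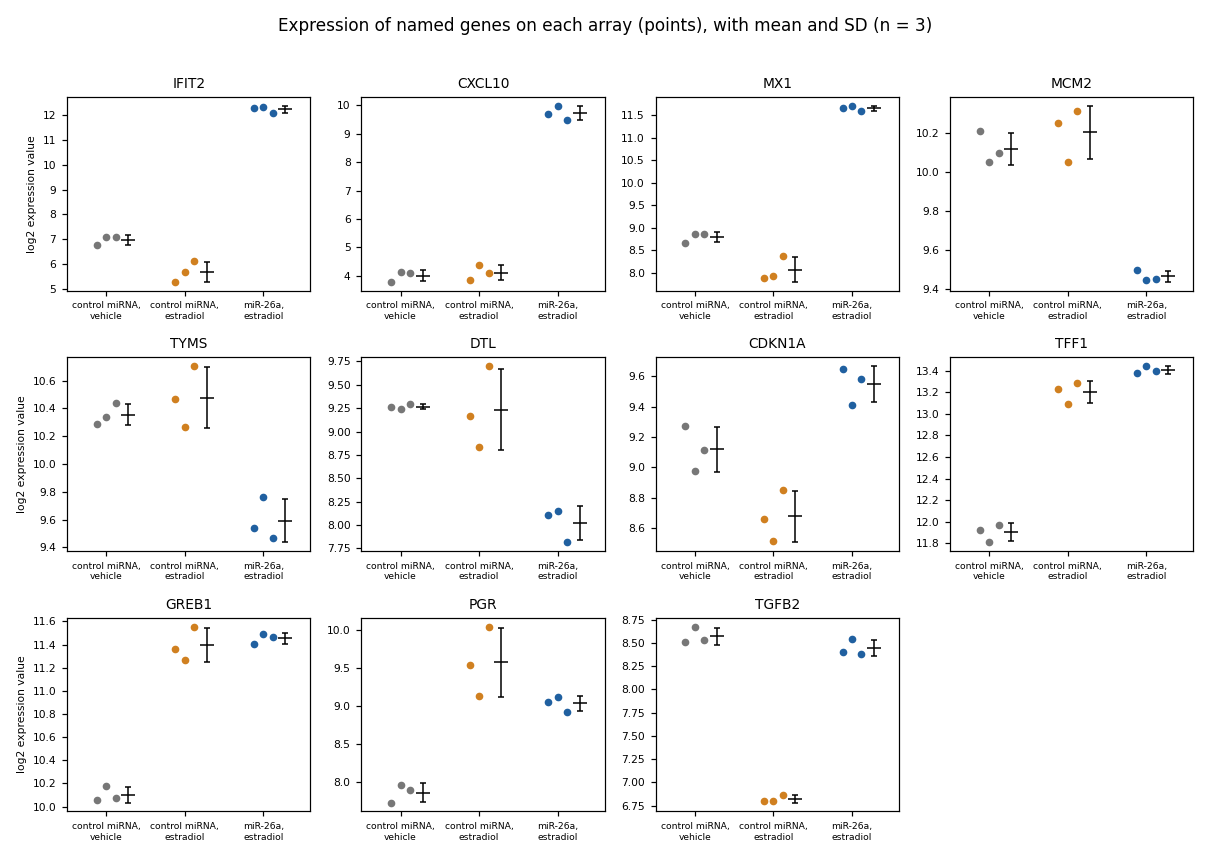
Log2 expression of 11 named genes on each of the 9 arrays (points), with the mean and SD of each group of 3 beside them; each panel has its own vertical axis. IFIT2 averaged 12.23 with miR-26a against 5.70 with the control miRNA under estradiol, MCM2 9.46 against 10.20, and TFF1 13.20 with estradiol against 11.90 with vehicle.

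Estradiol raised known estrogen-induced genes in control miRNA cells. TFF1, a secreted trefoil protein gene and a standard estrogen receptor target (transcript cluster 3933559), rose 2.46-fold from 11.90 ± 0.08 to 13.20 ± 0.10 (log2 difference 1.30, SE 0.073, limma adjusted p = 0.000368, n = 3 per group). GREB1, an estrogen receptor cofactor gene, rose 2.45-fold (adjusted p = 0.000814), the progesterone receptor gene PGR 3.27-fold (0.00831), the transcription factor gene EGR3 2.94-fold, RAPGEFL1 2.30-fold and the chemokine gene CXCL12 2.04-fold. Of 35 measured estrogen-induced genes 15 rose and 1 fell; adjusted over the list alone 19 rose and 4 fell, with a median log2 difference of 0.40 (camera adjusted p = 7.29e-20; adjusted p = 0.291 with an estimated correlation). The member that fell was STC2 (-0.91), a secreted glycoprotein gene named after its value was seen. The PGR call was lost without replicate 1 of the control miRNA with estradiol or vehicle replicates 1 or 3 (adjusted p up to 0.0543) and with only the 6 arrays compared (0.0842). The largest rise was that of BMPER, a modulator of bone morphogenetic proteins (3.80-fold, adjusted p = 0.00121), followed by the cytokine gene IL20 (3.36-fold).

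Estrogen-repressed genes were lower with estradiol. TGFB2 fell by 1.75 on the log2 scale from 8.57 ± 0.09 to 6.82 ± 0.04 (SE 0.073, adjusted p = 0.000113, n = 3 per group), and CYP1A1, a xenobiotic-metabolising enzyme gene, fell by 1.56. The B-cell adaptor gene BLNK and YPEL3, a gene linked to growth arrest, fell by 0.92 and 0.76 (adjusted p = 0.00183 and 0.00121). Of 27 list members 11 fell and 1 rose, the semaphorin gene SEMA3B (0.58, named after its value was seen), and adjusted over the list alone 18 fell and 1 rose. The median was -0.45 (camera adjusted p = 6.93e-15; adjusted p = 0.232 with an estimated correlation), and -0.30 after quantile normalization. The integrin gene ITGB6 had the largest fall and fell by 2.32 from 8.34 ± 0.12 to 6.02 ± 0.26 (adjusted p = 0.000368), and EFEMP1, an extracellular matrix protein gene, fell by 1.97. The calcium-binding protein gene PVALB fell by 1.83, the membrane protein gene TM4SF1 by 1.75, TNFRSF11B, which encodes osteoprotegerin, by 1.71, the lactate receptor gene HCAR1 by 1.58 and the matrix metalloproteinase gene MMP16 by 1.55.

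Interferon and p53 target genes were somewhat lower with estradiol. IFIT2, OAS2, IFIT3 and MX1 fell by 1.29, 1.05, 1.26 and 0.73 on the log2 scale; of 27 interferon genes these 4 passed over all genes, 14 fell adjusted over the list alone, and the median was -0.53 (camera adjusted p = 8.29e-06; adjusted p = 0.527 with an estimated correlation). With the arrays' interquartile range as a covariate the median was -0.30. Each of the 4 calls was lost without any array but replicate 3 of the control miRNA with estradiol (adjusted p up to 0.126, 0.128, 0.186 and 0.199). Of 19 p53 target genes TP53INP1 fell by 0.73, 2 fell adjusted over the list alone, and the median was -0.27 (camera adjusted p = 0.000572; adjusted p = 0.891 with an estimated correlation). The p53 median was -0.14 and -0.43 without replicates 2 and 3 of the control miRNA with estradiol, -0.18 after quantile normalization and -0.09 with the covariate. The TP53INP1 call was also lost without any array but replicate 3 of the control miRNA with estradiol (up to 0.194). TP53INP1 is also on the estrogen-repressed list.

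Cell cycle lists had no stable direction with estradiol at 48 h. None of 39 G1/S and DNA replication genes passed over all genes or adjusted over the list alone by limma, and the list had a median of 0.004, a mean of -0.017 and an upward camera direction (adjusted p = 0.27). That median was 0.14 and -0.17 without replicates 2 and 3 of the control miRNA with estradiol, and the list passed without replicate 2 (2.35e-06), after quantile normalization (median 0.15, 0.00105), with the arrays' interquartile range as a covariate (0.19, 9.17e-13) and with the stricter filter on dim clusters (0.01, 0.00199). Of 35 G2/M and mitosis genes AURKB rose under both adjustments (0.35, adjusted p = 0.0371), and the median was 0.06 (camera adjusted p = 0.00136; adjusted p = 0.891 with an estimated correlation). Without replicate 3 of the control miRNA with estradiol the mitosis list's call was lost and its median turned to -0.18 (adjusted p = 0.753). It also turned to -0.02 with array weights (0.317) and to -0.03 without replicates 2 and 3 of that group (0.274). The mitosis median was 0.13 and 0.23 without replicates 1 and 2 of that group, 0.02 and 0.10 without vehicle replicates 1 and 3, 0.19 after quantile normalization, 0.15 with arrays centred on their medians and 0.33 with the covariate. The AURKB call was lost without any array but replicate 3 of the control miRNA with estradiol (up to 0.181). MYC had a log2 difference of -0.35 (adjusted p = 0.121), CCND1 0.03 (0.853), ESR1 -0.37 (0.0783), EZH2 -0.06 (0.905), CCNE1 -0.41 (0.213), CCNE2 -0.32 (0.663) and CDKN1A -0.44 (0.166). The sign of EZH2 turned after quantile normalization (0.12), with arrays centred on their medians (0.025), without replicate 2 of the control miRNA with estradiol (0.12) and with the arrays' interquartile range as a covariate (0.20, adjusted p = 0.0387). That of CCNE2 turned with the covariate (0.14). Without replicate 3 of the control miRNA with estradiol MYC, ESR1, CCNE1 and CDKN1A passed (0.0081, 0.0185, 0.0122 and 0.0184), as they did with array weights (0.000837, 0.00351, 0.00227 and 0.00417). MYC also passed with the covariate (0.0364) and without replicates 2 and 3 of that group (0.0427).

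Among epithelial genes, estradiol lowered CLDN4, KRT80 and SPDEF by log2 differences of -1.41, -0.72 and -0.64 and raised TFF3 by 0.52. Of the 17 luminal genes 1 rose and 6 fell adjusted over the list alone, and the list did not pass (median -0.14, camera adjusted p = 0.0514). It passed after quantile normalization (0.0202), with arrays centred on their medians (0.02), with the trended and robust prior (0.0482), and without replicate 1 of the control miRNA with estradiol (0.0227) or vehicle replicates 2 (0.0288) or 3 (0.042). Of 11 basal and mesenchymal genes SNAI2 fell by 0.95 (adjusted p = 0.00639) under both adjustments, at a list median of 0.00 (camera adjusted p = 0.865). The KRT80, SPDEF and TFF3 calls were lost without any miR-26a or vehicle array or replicate 1 of the control miRNA with estradiol (adjusted p up to 0.12, 0.153 and 0.132), and that of SPDEF also without replicate 2 of that group.

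Of 31 literature miR-26a targets PGR rose, and PRKCD and CDK6 fell by 0.90 and 0.39, under both adjustments (list median -0.16, camera adjusted p = 0.302). CDK6 did not pass with arrays centred on their medians (0.193) or with only the 6 arrays compared (0.14). Of 17 hypoxia genes SLC2A1, a glucose transporter gene, rose by 0.39 and EGLN3 and HK2 fell by 0.93 and 0.50, under both adjustments (median -0.15, 0.671). These 5 calls other than that of PGR were lost without replicate 1 of the control miRNA with estradiol or vehicle replicates 2 or 3 (adjusted p up to 0.0737, 0.103, 0.173, 0.0657 and 0.17). Those of all but EGLN3 were also lost without vehicle replicate 1, that of CDK6 without miR-26a replicate 2, and those of SLC2A1 and HK2 without any miR-26a array.

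The remaining lists had no member past the threshold over all genes. By camera, 3 of them passed: cholesterol synthesis (median 0.07, adjusted p = 0.0328), markers of other cell types (0.07, 0.0102; median -0.01 with the arrays' interquartile range as a covariate) and RNA processing (-0.15, 0.0399), each with an adjusted p = 0.891 with an estimated correlation. Adjusted over the list alone, 0, 0 and 1 of their members passed, the last downward. After quantile normalization the cell type and RNA processing calls were lost (0.107 and 0.126). The RNA processing call was also lost with the covariate (0.956) and with the milder (0.134) or stricter (0.522) filter on dim clusters. The cholesterol call was lost without replicate 3 of the control miRNA with estradiol, where its median turned to -0.10 (0.742), without vehicle replicate 2 (0.0763), with array weights (0.124) and without replicates 2 and 3 of the control miRNA with estradiol (0.113). The cell type call was lost without replicate 2 of the control miRNA with estradiol (0.554), and the RNA processing call without replicates 1 or 2 of that group or vehicle replicates 2 or 3 (up to 0.702). Without replicates 2 and 3 of the control miRNA with estradiol in turn, the medians were 0.24 and -0.10 for cholesterol synthesis, 0.01 and 0.12 for other cell types and -0.04 and -0.28 for RNA processing. After quantile normalization they were 0.21, 0.11 and -0.02, with arrays centred 0.15, 0.15 and -0.07. Estrogen receptor and cofactor genes had a median of -0.05 (camera adjusted p = 0.671), with 1 higher and 2 lower adjusted over the list alone. No member passed adjusted over the list alone for miRNA pathway genes (-0.09, 0.651), ER stress genes (-0.08, 0.993), polycomb genes (-0.08, 0.618), ribosomal protein genes (-0.08, 0.798), ribosome biogenesis genes (-0.13, 0.377) and lysosome and autophagy genes (-0.11, 0.149).

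In total, estradiol changed 307 transcript clusters, 72 higher and 235 lower (23.5% higher), and 212 at a fold of at least 1.5, 50 higher and 162 lower. Groups did not overlap in 12.4% of clusters, where chance gives 10% only if all arrays vary alike. Here too the groups' spreads were unequal, so no excess over chance is read from it. ZNF385B, IGSF1 and ARHGAP36 were also among the 10 largest rises, at log2 differences of 1.72, 1.65 and 1.23, and CAB39L among the 10 largest falls at -1.61. The lower level of IGSF1, CAB39L, PVALB, TNFRSF11B, SNAI2, CDK6, ITGB6 and IFIT2 in this comparison lay under or within the 25th percentiles of the arrays, so their sizes of change are minimum values as well, with miR-26a too for TNFRSF11B, SNAI2 and ITGB6. After quantile normalization the count was 485, 191 higher and 294 lower (39.4% higher), and with arrays centred on their medians 381 (33.9% higher). At 1.5-fold the shares higher were 23.6%, 34.3% and 32.8%. The count was 143, 146 and 157 without miR-26a replicates 1, 2 and 3, 90 and 5345 without replicates 1 and 3 of the control miRNA with estradiol, and 94, 100 and 86 without vehicle replicates 1, 2 and 3. At 1.5-fold these 8 counts were 115, 122, 126, 81, 2111, 86, 90 and 76. Without replicates 2 and 3 of the control miRNA with estradiol 1007 and 591 were called. With only the 6 arrays compared, a fit with fewer arrays, 45 clusters were called, all at 1.5-fold or more. The interquartile range covariate gave 935 (45.3% higher), and array weights gave 8182 and 1517 at 1.5-fold. Of 39 calls among named genes 22 held whichever array was left out and 17 were lost at least once, among them ZNF385B without replicate 1 of the control miRNA with estradiol or any vehicle array (adjusted p up to 0.0756) and CAB39L without any array but replicate 3 of that group (up to 0.162).

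**Figure D2:**
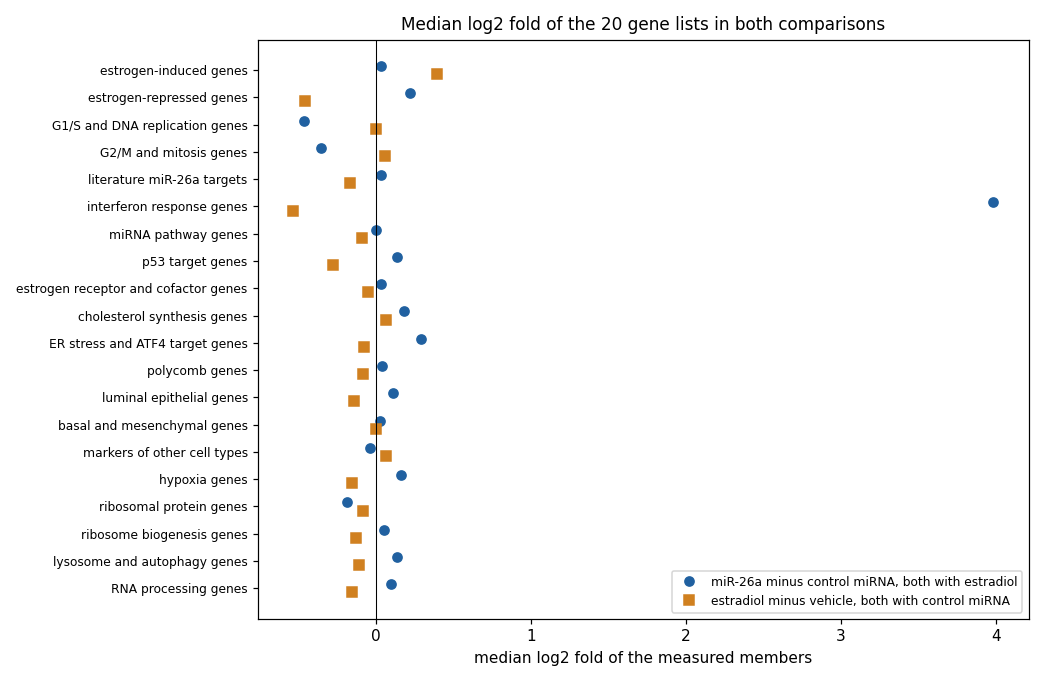
Median log2 fold of the measured members of each of the 20 gene lists (horizontal axis), for miR-26a against control miRNA under estradiol (circles) and for estradiol against vehicle with control miRNA (squares). The interferon list lies at 3.98 in the first comparison and -0.53 in the second, and the G1/S and DNA replication list at -0.46 and 0.004.

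Genes that estradiol lowered and miR-26a raised included TGFB2 (log2 differences -1.75 with estradiol and 1.63 with miR-26a), ITGB6 (-2.32 and 1.98), EFEMP1 (-1.97 and 1.52) and TNFRSF11B (-1.71 and 3.45). DEPTOR (1.07 and -1.08) and SFXN2 (1.16 and -1.03) went the other way. Against vehicle, a comparison added after the data were seen, the miR-26a group differed by -0.13 for TGFB2, -0.34 for ITGB6, -0.45 for EFEMP1, -0.01 for DEPTOR and 0.13 for SFXN2, none past the threshold, and by 1.74 for TNFRSF11B (adjusted p = 0.000243). Each of these values is the sum of the gene's estradiol and miR-26a differences. The genes were named for opposite signs, so closeness to vehicle is no separate test of a return to its level. The named opposed genes of largest combined size were IFIT2, IFIT3, OAS2, TNFRSF11B and MX1, of which all but TNFRSF11B are on the interferon list. All were above vehicle past the threshold, by 5.249, 4.816, 4.005, 1.739 and 2.851. In all, 100 clusters passed in both comparisons with opposite signs, 86 lower with estradiol and higher with miR-26a and 14 the reverse, where independent lists would share 7.47 and 0.631, and 12 passed with the same sign (7 higher and 5 lower, where independent lists would share 2.29 and 2.06). The control miRNA arrays with estradiol enter both comparisons with opposite signs, and unchanged groups simulated against them gave a mean of 8.7 opposed clusters (0 to 33 in 100 simulations). They gave a mean of 0.01 clusters with the same sign (0 to 1), and each cluster was drawn independently. The covariance of the log2 differences was -0.0368 against -0.0367 in those simulations (-0.0392 to -0.0346), and the correlation was -0.411 against -0.781. These 3 arrays are too few to be split, so the part of the excess that comes from the shared arrays was not separated. The count was 38, 43 and 42 without miR-26a replicates 1, 2 and 3, 29 and 2484 without replicates 1 and 3 of the control miRNA with estradiol, and 36, 35 and 35 without vehicle replicates 1, 2 and 3. It was 194 after quantile normalization, 15 with only the 6 arrays of each comparison, 476 with the interquartile range covariate, 3733 with array weights and 455 without replicates 2 and 3 of the control miRNA with estradiol.

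**Figure D3:**
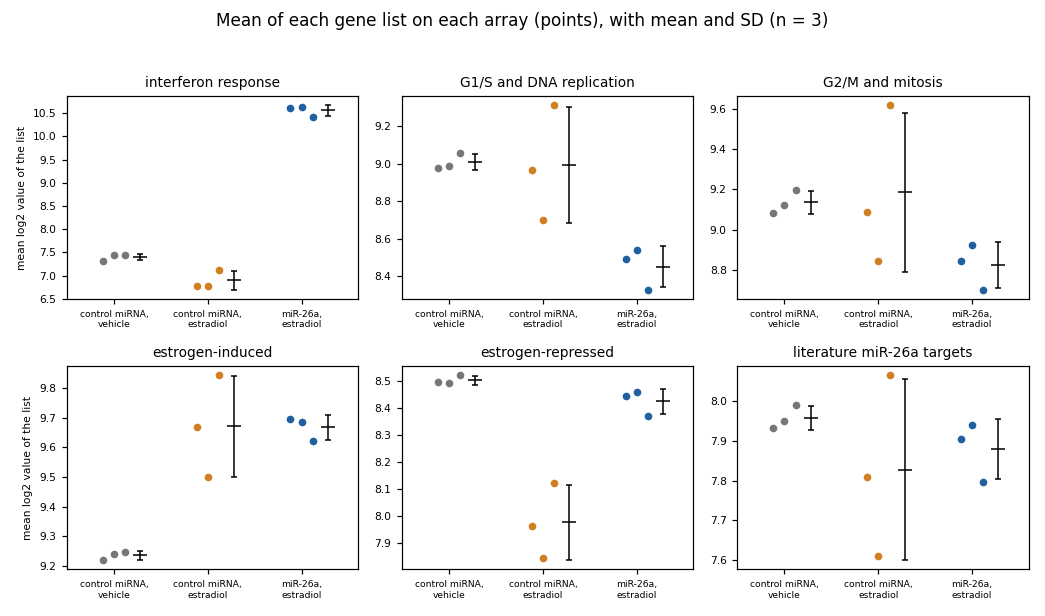
Mean log2 value of 6 gene lists on each of the 9 arrays (points), with the mean and SD of each group of 3 beside them; each panel has its own vertical axis. The interferon list averaged 10.56 with miR-26a, 6.89 with the control miRNA and estradiol and 7.40 with vehicle, and the estrogen-induced list 9.67, 9.67 and 9.24.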

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

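Of these alternatives, the interquartile range covariate, the fit without replicates 2 and 3 of the control miRNA with estradiol, and the gene-by-gene method for array weights (the default did not converge) were chosen only after the data were seen. The test of genes with miR-26a seed sites was not run, since it needs transcript sequences not used here, and a pseudocount did not apply to log2 values. Of the 893 miR-26a calls, 792 were called again after quantile normalization. With the replicate number as a block the miR-26a comparison called 613 clusters, the estradiol comparison 94 and 86 at 1.5-fold, and 34 were opposed. The numbers share no pairing in the labels, and of 9 same-numbered pairs 3 had deviations that correlated above 0.1 (-0.44 to 0.27), with 4 of 9 arrays closest to their own number. Quantile normalization gave 1511 and 485 clusters and 194 opposed. Only the 6 arrays compared gave 437 for miR-26a, and 45 for estradiol with or without the 1.5-fold limit, and 15 opposed; this fit has fewer arrays. Array weights gave 5817 and 8182 clusters, 1373 and 1517 at 1.5-fold, and 3733 opposed. The weights on the 3 control miRNA arrays with estradiol were 6.41, 0.242 and 0.145, so that 1 array carried most of the weight in this group. The interquartile range covariate gave 3182 and 935, and 476 opposed. Without replicates 2 and 3 of the control miRNA with estradiol the counts were 1363 and 1007, 591 at 1.5-fold for estradiol, and 455 opposed, with the lone array assumed to vary like the other groups. A fold of 1.5 alone gave 1126 and 967, and a fold of 2 gave 279 and 77. With single arrays left out the ranges were 521 to 3719 and 86 to 5345, at 1.5-fold 425 to 1641 and 76 to 2111, and opposed 29 to 2484; each highest count came without replicate 3 of the control miRNA with estradiol. The cause of these moves was not tested. With an estimated correlation 1 list passed for miR-26a and 0 for estradiol, against 8 and 8. The direction of the test or fit was reversed for the mitosis list with estradiol without replicate 3 of the control miRNA with estradiol (-0.18, against 0.234 without replicate 2), the markers of other cell types with estradiol under the covariate (-0.01) and EZH2 with estradiol under the covariate (0.20, adjusted p = 0.0387). Of the fixed named genes, EZH2 with estradiol also turned sign under both scalings and without replicate 2 of the control miRNA with estradiol, CCNE2 with estradiol under the covariate and GREB1 with miR-26a with arrays centred or without that replicate 2, none of them called in either fit. Medians of called lists also turned sign for cholesterol synthesis with estradiol without that replicate 3 (-0.097), for the mitosis list with estradiol under array weights (-0.023) and without replicates 2 and 3 (-0.028), and for the basal and mesenchymal list with miR-26a when arrays were centred on their medians (-0.043). The cause of these turns was not tested. In the next counts a turn of direction was a change only where at least 1 of the 2 fits passed. Of 360 list values with an array left out 342 stayed on their side of the threshold, 10 lost and 7 gained a call. Of 480 under the other alternatives 438 stayed, 33 lost and 8 gained. For named genes these counts were 1571 of 1818 (194 lost, 53 gained) and 1751 of 1977 (81 lost, 144 gained).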

Other observations

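The antigen presentation and leukocyte lists, and the tests of array distributions, leukocytes, target loss, return to the vehicle level and gene span, were chosen only after the results were seen. Genes of antigen presentation rose with miR-26a. Of 19 measured members 16 rose and 17 did so within the list alone, with a median log2 difference of 1.36 (camera p = 3.37e-30; p = 0.000283 with an estimated correlation). TAP1, which carries peptides into the endoplasmic reticulum, rose 8-fold from 7.82 ± 0.22 to 10.82 ± 0.09 (SE 0.109 on the log2 scale, limma adjusted p = 2.9e-06, n = 3 per group), and its partner TAP2 rose 4.51-fold. B2M, the common light chain of class I molecules, rose 6.41-fold, the class II invariant chain gene CD74 6.45-fold, the immunoproteasome gene PSMB8 4.76-fold, and the non-classical class I genes HLA-F and HLA-E 4.48-fold and 2.55-fold. CANX (-0.03), PSME2 (0.98) and HLA-DMB (0.27) did not pass. None of the 19 passed with estradiol by limma over all genes, and 4 were lower within the list alone.

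The rise of interferon genes with miR-26a was set against the uneven control arrays, leukocytes in the culture and the loss of miR-26a targets. Against vehicle, which leaves those control arrays out but differs in estradiol too, the list's median was 3.125. In the list mean those control arrays lay at 6.89 ± 0.20 against 10.56 ± 0.12 with miR-26a, a gap far beyond their spread. Uneven control arrays are thus argued against as its source. Leukocyte transcripts had a median of -0.03 over 23 genes, of which S100A8, LCP1 and CD68 rose and ARHGDIB fell; leukocytes would bring their transcripts together, so the median argues against them, and 6 of the genes are also in the list of other cell types. Literature targets showed no shift (camera adjusted p = 0.928) but went both ways, so an effect through target loss stays open. A hypothesis that sensing of the transfected miR-26a duplex itself may raise these genes also stays open, since only 1 miR-26a and 1 control miRNA were used; a duplex with a changed seed would be its test.

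The lower level of DNA replication genes with miR-26a was set against the uneven control arrays and a return to the level without estradiol. Against vehicle the median was -0.566, but in that comparison estradiol differs as well as the miRNA. The effect of estradiol on the list was measured only with the uneven arrays, so this value cannot exclude them as a source. Without each control miRNA array with estradiol the median stayed at -0.351 or lower, so no 1 of these arrays alone accounts for it. The highest miR-26a array lay 0.441 below the lowest vehicle array in the mean of the list (-0.441). In the main fit the control miRNA groups gave no estradiol rise to return from (8.99 ± 0.31 against 9.01 ± 0.04 with vehicle). This result therefore follows from the fall itself and is no separate test. The list's call was lost with an estimated correlation (adjusted p = 0.331).

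The wide spread of the 3 control miRNA arrays with estradiol was set against array scaling and a trend with gene span. After quantile normalization the group's median SD was still 2.13 times the higher of the other groups, so scaling is argued against. A joint trend on gene span and intensity, fitted to unscaled values, removed 34.2% of the variance of the difference between replicates 2 and 3. It covered 14208 of 14232 genes (99.8%), with a Spearman correlation across genes of -0.26 with span and -0.55 with intensity. The interquartile ranges of these arrays, 2.44 and 2.83, also bring a trend with intensity, so the share of gene span was not separated. The 34.2% lies between the bounds set for the test and decides nothing. RNA or labelling differences between these cultures stay a possible explanation. No biological explanation was tested, since all 3 arrays carry the same group label.

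The covariance of the 2 sets of log2 differences, -0.0368, lay within the simulations of unchanged groups (-0.0392 to -0.0346). The count of opposed clusters, 100, lay above theirs (0 to 33). The simulations drew each cluster independently, whereas the spread of whole arrays differed among the 3 shared ones. Their ranges may therefore be too narrow to judge either value, and a reversal of estradiol effects beyond the shared arrays stays undecided. Splitting the 9 arrays in 100 ways gave 100 or more opposed clusters in 2 splits, the real one and one with 404. In the latter the 3 miR-26a arrays were the shared group, so their difference from the others entered both comparisons with opposite signs, and its count decides nothing. Splits that scatter the 3 miR-26a arrays raise the spread within groups and decide nothing either, and the 6 splits that keep these arrays together are too few for a share under 0.05. For each comparison alone, the 10 splits of 6 arrays are too few for a share under 0.05. The real counts were 893 and 560 at 1.5-fold for miR-26a, against 3 and 2 in the highest other split. For estradiol they were 307 and 212 against 0 and 0. The other splits mix arrays of the compared groups, which raises the spread within groups, so their low counts decide nothing. For gene lists the real counts were 8 and 8 and the highest other 11 and 11, with as many lists in 8 and 7 of the 10 splits. The number of lists called thus did not set the real grouping apart from other splits of the same arrays.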
